A study of Mus musculus with 24 samples.

How the data were processed

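The samples are 24 Affymetrix arrays of mouse RNA. They hold 3 normal cerebella (2 at P6, postnatal day 6, and 1 adult), 3 primary medulloblastomas (MB) of Ptch1 mutant adult mice, and 18 cultures of 3 SMB lines. SMB lines were derived from medulloblastomas of Ptch heterozygous mice and grow as neurospheres in serum-free medium. The 8 parental arrays are 4 of SMB21, 2 of SMB55 and 2 of SMB56. The growth factor (GF) group has 1 array per line, from cells kept for over 3 weeks with EGF at 20 ng/mL and bFGF at 20 ng/mL. The 7 arrays of RAS transformed cells are 3 of SMB21, 2 of SMB55 and 2 of SMB56. Groups were read from the titles and labels and not from the values. For P6 replicate 2 the age in the labels conflicts with the title, and the title was followed. The titles call the replicates biological, but nothing says which cultures or animals they came from.

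Per the labels, total RNA was biotin labelled and hybridized by the manufacturer's protocol. The deposited values are 1 linear summary intensity per probe set and array, brought by the authors to nearly the same distribution on every array. How the intensities were summarised and normalised is not given in the sources used here. Array medians lie between 188.8 and 245.1, upper quartiles between 890.5 and 1006.0, and single values between 10.0 and 37842, with 0 missing. An array has no read depth. Its precision depends on signal over background, so changes of genes near the lowest intensities are compressed.

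Of 22690 probe sets, 20393 have 1 gene symbol, 691 have several and 1606 have none, and 64 are hybridization controls. By gene identifier, 20364 probe sets matched the GRCm38.p6 gene table, which served only for names and for the chromosome of each gene. 0 symbols changed. For the 4958 genes with more than 1 probe set, the probe set with the highest mean over all arrays was kept. That left 12394 genes. Probe sets without a single symbol were tested apart. Values were used as log2 of the intensity plus 16, and every change below is a difference of such values. Some genes of the planned lists were not analysed here.

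Linear models were fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation, two-sided tests and Benjamini-Hochberg adjustment over the 12394 genes. A gene is called changed at an adjusted p under 0.05. Tissues were compared in a fit of the 3 cerebella, the 3 tumors and 3 values for parental SMB cells, 1 mean per line. Cultures were compared in a fit of the 18 cell arrays with the treatment and the line as terms. Arrays of 1 line thus count as separate replicates there, so the p-values hold for these 3 lines and not for lines in general. A fit with a mean for each of the 9 combinations of line and treatment tested whether a response differs by line. The test for RAS was chosen before the data were examined and the test for growth factors after. The GF arrays, all numbered 1, correlated with parental array 1 of their line at 0.216, 0.339 and 0.104 in SMB21, SMB55 and SMB56, as deviations from the treatment means, which include the line. Each lies above 0.1, so the numbers were taken to pair these arrays, though in SMB21 and SMB56 parental replicate 2 correlated more highly. In the other comparisons the pairs did not all lie above 0.1. For RAS against parental cells the deviations were taken from the mean of each line and treatment, which leaves the line out. Those values are therefore not comparable with the GF ones, which a shared line alone can raise. Where groups are called non-overlapping, each array of 1 group lies above or below each array of the other.

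The 23 gene lists were fixed before the data were examined, as were the comparisons, the tests, the threshold and most alternatives. They cover Shh pathway targets, Shh pathway components, primary cilium, ERK pathway targets and feedback, growth factor receptors and RAS pathway, granule neuron precursors, mature granule neurons and neuronal differentiation. They also cover neural stem and progenitor cells, astrocytes, oligodendrocyte lineage, Purkinje cells and inhibitory neurons, microglia and macrophages, endothelium and pericytes, fibroblasts and meninges, and red blood cells. The others are proliferation, invasion and mesenchymal genes, Wnt pathway targets, p53 targets, interferon response, glycolysis and hypoxia, and cholesterol synthesis. Each list was tested against all other genes with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, which tests a list without reference to other genes. List p-values are adjusted over the 23 lists.

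The rule for named genes was also fixed then. It takes the 6 largest rises and the 6 largest falls among called genes whose higher group mean reaches the median of all genes, 8.36, and whose arrays do not overlap, in cultures within each line. Predicted genes with clone-like names are passed over. It adds up to 3 called members of each list by the smallest p, and always Gli1, Ptch1, Hhip, Mycn, Ccnd1, Smo, Sufu, Atoh1, Dusp6, Spry4, Etv5 and Nras.

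The alternatives were quantile normalization, median centring, a pseudocount of 64, the mean of all probe sets of a gene, omission of the lowest 33.3% of genes, another variance prior, an added 2-fold limit, fits of only the groups compared, and fits without the line. Further ones were 1 mean per line, replicate numbers as a block, P6 or adult cerebella alone, parental arrays split by number, and omission of each array and each line. Those added after the data were examined are named in the closing section. Comparisons that share controls were set beside simulations of unchanged groups and beside the overlap of independent lists. Other splits of the samples were counted, all of them where there were at most 100. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.

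The fits were tested on simulated data of 12394 genes, of which 200 were changed. The noise was drawn independently for each gene and array. The shares and counts below therefore do not cover arrays of a line, or genes, that vary together. For the comparison of MB with normal cerebellum the fit called 46% of 2-fold and 81% of 4-fold changes, and 9 unchanged genes. The shares were 57% and 80% with 11 unchanged genes for SMB cells against MB, and 43% and 76% with 5 for SMB cells against normal cerebellum. Those for GF against parental cells were 64% and 89%, with 7. The fit of RAS against parental cells called 78% and 98%, with 11, and that of RAS against GF 69% and 89%, with 5. A wrong direction was called for 0 genes. The test by line called 64% of changed and 6 unchanged genes, and camera called 1 list besides the changed one.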

Results

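The series asks 2 questions of these arrays. SMB cells were first compared with primary medulloblastoma and normal cerebellum, and then with SMB cells kept in growth factors or transformed with RAS. Values are log2 differences with their standard error (SE), p-values are limma's adjusted ones, and group levels are log2 means with their SD.

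Primary medulloblastomas (n = 3) differed from normal cerebella (n = 3) in single Hedgehog genes, in Cdkn2a and in markers of Purkinje cells and astrocytes. The mature granule neuron list passed neither camera nor fry. Gli1, a transcription factor that is itself induced by Hedgehog signalling, rose by 2.03 (SE 0.36, 4.08-fold, adjusted p = 0.0173), from 7.60 (SD 0.64) to 9.63 (SD 0.41). Boc, a Hedgehog co-receptor, rose by 1.59 (SE 0.20, adjusted p = 0.00412). Cdkn2a, which encodes inhibitors of the cell cycle, rose 62.1-fold (5.96, SE 0.19, adjusted p = 8.38e-06), and Prm1, a protamine of sperm chromatin, 73.6-fold (6.20, SE 0.93, adjusted p = 0.00858). The glycolytic enzyme Hk2 rose by 3.65 (SE 0.46), and the transcription factors Foxa2 and Lhx2 by 4.05 and 3.51. The largest falls were of Car8 (-7.56, SE 0.86), Calb1 (-6.98, SE 0.79) and Pcp2 (-6.30, SE 0.68), which mark Purkinje cells, and of Ttr (-6.93, SE 0.53), the transthyretin of the choroid plexus.

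Among the lists, 9 of 15 astrocyte genes fell and 0 rose (11 fell when adjusted over the list alone; camera adjusted p = 2.52e-10, and adjusted p = 0.178 with an estimated correlation). Aldh1l1, a folate enzyme of astrocytes, fell by 4.79 (SE 0.13), and the water channel Aqp4 fell by 5.66 (SE 0.44). Of the fibroblast and meninges genes 8 of 13 fell (13 adjusted over the list alone; camera adjusted p = 5.83e-11, and adjusted p = 0.113 with an estimated correlation), with Aldh1a2, an enzyme of retinoic acid synthesis, at -2.71 (SE 0.11) and Foxc1 at -2.43. Of the Purkinje cell genes 6 of 12 fell (8 adjusted over the list alone; camera adjusted p = 3.12e-06, and adjusted p = 0.353 with an estimated correlation). Microglia and macrophage genes went the other way. Of 18, 9 rose and 1 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.0025, and adjusted p = 0.631 with an estimated correlation). Lysozyme Lyz2 rose by 2.99 (SE 0.44), the lysosomal protein Cd68 by 1.87 (SE 0.20) and complement C1qc by 1.11, while P2ry12, a receptor of resting microglia, fell. Proliferation genes had a median of 1.76 over 32 members, of which only Foxm1 passed on its own, at 1.82 (0 adjusted over the list alone; camera adjusted p = 0.00018, and adjusted p = 0.631 with an estimated correlation). Against P6 cerebella alone the list had a median of 0.48 and 5 rises. Foxm1 lost its call without P6 replicate 2 (adjusted p = 0.076), without tumor 1, 2 or 3 (0.0866, 0.119 and 0.116) and without line SMB21, SMB55 or SMB56 (0.0599, 0.0607 and 0.0679).

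Of the 10 Shh pathway targets, Gli1 and Sfrp1 rose and Igf2 and Rab34 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.462). Igf2, an insulin-like growth factor, fell by 4.22 (SE 0.51) and Sfrp1, a secreted Wnt antagonist, rose by 2.98 (SE 0.61, adjusted p = 0.0272). Of the 8 pathway components Boc and Smo rose (5 adjusted over the list alone; camera adjusted p = 0.0038, and adjusted p = 0.379 with an estimated correlation; 1 rose against P6 cerebella alone), Smo, the signal transducer of the pathway, by 1.10 (SE 0.25, adjusted p = 0.0383). Several of these calls depend on single arrays. The adjusted p of Gli1 was 0.0598 without tumor 2 and 0.0633 without tumor 3. That of Sfrp1 was 0.0531 without P6 replicate 2 and 0.0714, 0.0618 and 0.097 without tumor 1, 2 and 3. That of Smo was 0.0638 and 0.0955 without P6 replicate 1 and 2, 0.0678 without the adult cerebellum, 0.0833 and 0.0998 without tumor 2 and 3, and 0.0516 and 0.0653 without line SMB55 and SMB56. A fit of only the 2 groups also ended the calls of Sfrp1, Smo and Foxm1 (0.0699, 0.076 and 0.0939), and P6 cerebella counted as 1 sample those of Smo and Foxm1 (0.0784 and 0.0557). Ptch1, the Hedgehog receptor gene that is mutated in these mice, did not pass (-0.06, SE 0.40, adjusted p = 0.944), nor did Hhip (0.83), Mycn (2.06, SE 1.07) or Sufu (1.65). Atoh1, a transcription factor of granule neuron precursors, was 3.14 higher (SE 0.96, adjusted p = 0.0832) and Ccnd1, a cyclin, 1.69 higher (SE 0.44, adjusted p = 0.0565). The size of these differences varied with the control, of which only 1 is adult. Without the adult cerebellum both passed, Atoh1 at 1.91 (adjusted p = 0.0346) and Ccnd1 at 1.09 (adjusted p = 0.0012). With the same controls both also passed in a fit of all 8 parental arrays with the line as a random block (adjusted p = 0.0257 and 0.0169). Ccnd1 passed with centred arrays too (1.78, adjusted p = 0.0428), without the lowest genes (0.0474) and with another variance prior (0.0488). Against the adult cerebellum alone, which is 1 array, Atoh1 stood at 5.61, Mycn at 4.85, Ccnd1 at 2.90 and Sufu at 3.18. The feedback genes of ERK signalling Dusp6 (-0.08), Spry4 (0.06) and Etv5 (0.43), and the RAS gene Nras (0.79), did not pass. Nras stood at 1.65 against the adult cerebellum alone.

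In all, 1076 genes changed between medulloblastoma and normal cerebellum, 434 higher and 642 lower, 649 of them at least 2-fold. With each array centred on its median the split was 608 higher and 548 lower. The count was 3066 against the adult cerebellum alone and 514 with both P6 cerebella counted as 1 sample. It was 652 and 433 without P6 replicate 1 and 2, and 547, 549 and 409 without tumor 1, 2 and 3. Chromosome 6 genes had a median 0.44, 0.67 and 0.33 above P6 cerebellum in tumors 1, 2 and 3.

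**Figure D1:**
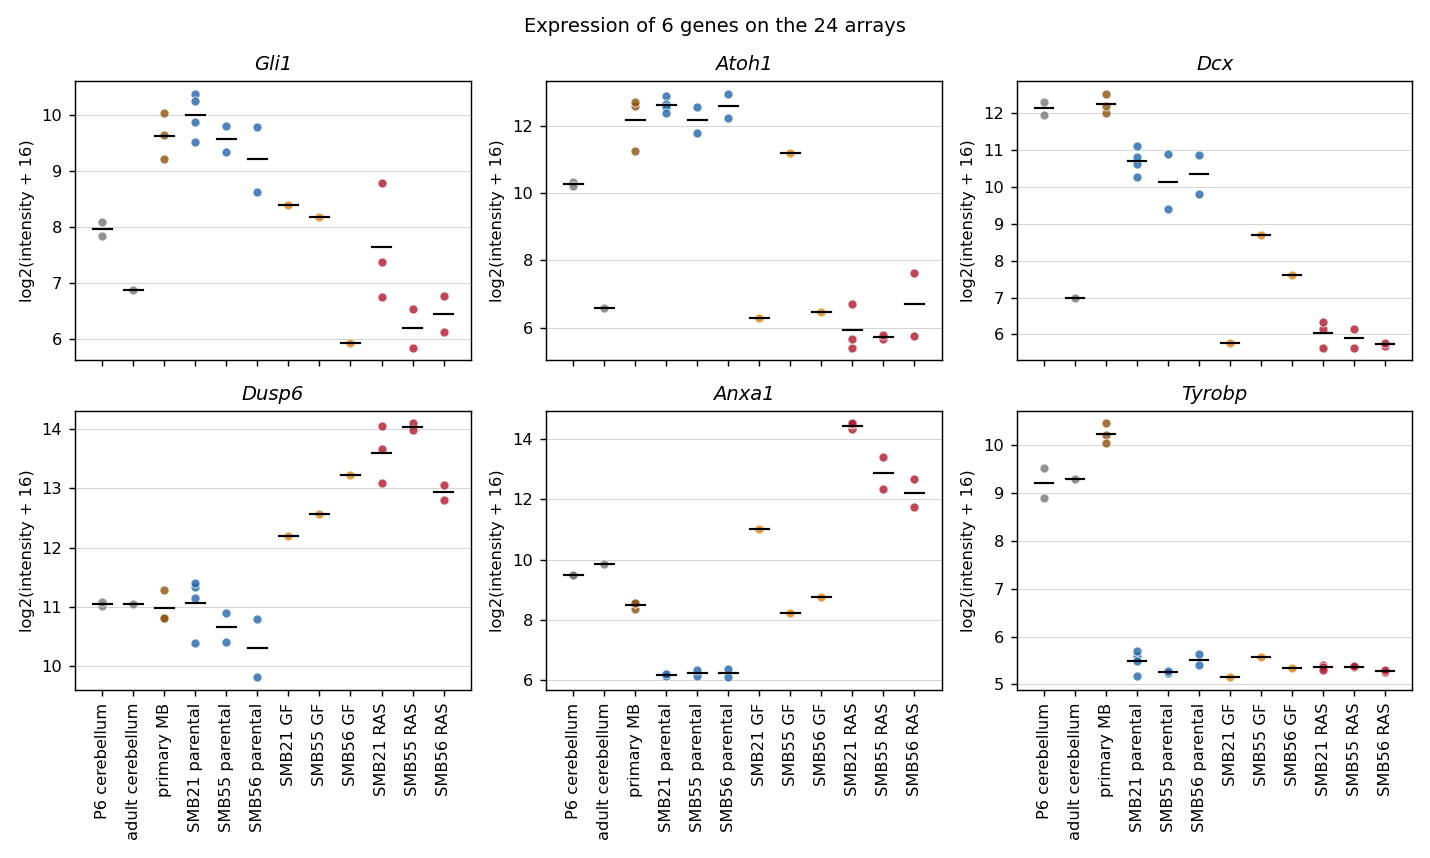
Level of 6 genes on each array, as log2 of the intensity plus 16, by group, with a bar at each group mean. Tyrobp, a microglial gene, is high in tissues and near the lowest values in cultures. Atoh1 and Dcx lie below the parental mean in the GF and RAS cells of each line, in SMB55 further below with RAS.

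Parental SMB cells (3 line means) had much lower levels of microglial and neuronal markers than the tumors (n = 3). Of the genes that are always named, only Etv5 passed. Gli1 differed by -0.03 (SE 0.36, adjusted p = 0.967), Ptch1 by -0.32 (SE 0.40), Atoh1 by 0.28 (SE 0.96), Mycn by -1.13 (SE 1.07), Ccnd1 by -0.23 (SE 0.44), Smo by 0.14 (SE 0.25), Hhip by 0.63 (SE 0.53) and Sufu by -0.90 (SE 0.59), and Sufu passed without the adult cerebellum (-0.90, adjusted p = 0.0282). The lysozyme gene Lyz1 fell by 7.75 (SE 0.38, 216-fold lower, adjusted p = 5.48e-05). The cathepsin gene Ctss (-6.89, SE 0.66) and Tyrobp, an adaptor of microglial receptors (-4.81, SE 0.18, adjusted p = 3.74e-05), fell as well. Bex1 (-6.90, SE 0.39) and Stmn2, which regulates microtubules in neurons (-5.77, SE 0.28), fell too. The largest rises were of Wif1, a secreted Wnt inhibitor (3.78, SE 0.49, 13.7-fold, adjusted p = 0.00517), Cth, an enzyme of cysteine synthesis (3.59), and the stress gene Trib3 (3.25, SE 0.29). Etv5, a transcription factor induced by ERK signalling, rose by 2.23 (SE 0.22, adjusted p = 0.00159).

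All of the 18 microglia and macrophage genes except 2 fell in SMB cells, 16 over all genes and 17 adjusted over the list alone (camera adjusted p = 6.77e-26, and adjusted p = 0.211 with an estimated correlation). Neuronal differentiation genes fell in 8 of 16 (10 adjusted over the list alone; camera adjusted p = 7.56e-08, and adjusted p = 0.211 with an estimated correlation). Among endothelial and pericyte genes 4 of 15 fell (6 adjusted over the list alone; camera adjusted p = 5.57e-05, and adjusted p = 0.564 with an estimated correlation), with the pericyte genes Rgs5 at -4.52 (SE 0.49) and Pdgfrb at -2.12 (SE 0.20). Of the granule neuron precursor genes 2 of 13 fell (2 adjusted over the list alone; camera adjusted p = 0.0122, and adjusted p = 0.828 with an estimated correlation), led by the neuronal transcription factor Neurod1 at -3.37 (SE 0.27, adjusted p = 0.000651). SMB21 parental replicate 1 stood above the other SMB21 arrays in Neurod1 (12.32 against 9.58 to 9.97) and in Stmn2 (8.67 against 6.24 to 6.63). Of 13 mature granule neuron genes 2 fell (1 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.0083, and adjusted p = 0.82 with an estimated correlation). The invasion and mesenchymal list had 8 falls and 1 rise in 30 (10 and 3 adjusted over the list alone; camera adjusted p = 0.0153, and adjusted p = 0.445 with an estimated correlation), among them Anxa1 (-2.28) and the galectin Lgals3 (-3.66), both also made by macrophages. Centring the arrays ended the camera calls of the precursor, mature granule neuron and invasion lists.

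Genes of cholesterol synthesis rose in 7 of 14 (12 adjusted over the list alone; camera adjusted p = 3.2e-07, and adjusted p = 0.445 with an estimated correlation), with Msmo1 at 1.91 (SE 0.15, adjusted p = 0.000609) and Fdps at 1.96 (SE 0.31). Glycolysis and hypoxia genes rose in 9 of 21 (12 adjusted over the list alone; camera adjusted p = 0.000179, and adjusted p = 0.445 with an estimated correlation), with the oxygen-sensing hydroxylase Egln3 at 2.47 (SE 0.33) and Pgam1 at 1.23 (SE 0.18). The Shh targets had 2 rises (3 adjusted over the list alone), a median of -0.13, a mean of 0.18 and an upward test (camera adjusted p = 0.728), and the Shh components 1 rise (1; 0.728). Proliferation genes had 1 call in 32 (0 adjusted over the list alone), and Dusp6 (-0.30), Spry4 (0.02) and Nras (0.06) did not pass. In all 1373 genes changed, 838 higher and 535 lower, 694 at least 2-fold. With centred arrays the split turned to 477 higher and 1244 lower, as centring shifts all genes by -0.21, so that the rises above stand relative to that shift. The count was 2553 without the adult cerebellum, 612 and 598 without tumor 1 and 3, and 589 without line SMB56.

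Against normal cerebellum (n = 3), SMB cells (3 line means) had higher levels of several Hedgehog genes and lower levels of markers of other cell types. Gli1 rose by 2.00 (SE 0.36, adjusted p = 0.00892), Boc by 1.90 (SE 0.20), Smo by 1.25 (SE 0.25, adjusted p = 0.0133) and Atoh1 by 3.42 (SE 0.96, adjusted p = 0.0384). Cdkn2a rose 89.9-fold (6.49, SE 0.19), Etv5 by 2.67 (SE 0.22), the Notch ligand Dll3 by 3.65 and the translation repressor Eif4ebp1 by 3.48 (SE 0.42). The largest falls named here were of Bex1 (-8.20, SE 0.39), Calb1 (-7.99, SE 0.79), Aqp4 (-7.72, SE 0.44) and the connexin Gja1 (-7.26, SE 0.42). Aqp4 lay at 5.01 to 5.03 in all SMB21 parental arrays but replicate 1, close to the lowest intensities, so the size of its fall is compressed. The call of Atoh1 was lost without tumor 1 or 3 (adjusted p = 0.0591 and 0.0607) and without line SMB21, SMB55 or SMB56 (0.0993, 0.0753 and 0.101), and in a fit of only the 2 groups (0.083). Ptch1 (-0.38, SE 0.40), Mycn (0.94), Hhip (1.46), Sufu (0.75), Nras (0.84), Dusp6 (-0.38) and Spry4 (0.08) did not pass, nor did Ccnd1 (1.46, adjusted p = 0.0506), which passed without P6 replicate 1 (1.79, adjusted p = 0.042) and without the adult cerebellum (0.86, adjusted p = 0.00205). Against the adult cerebellum alone, which is 1 array, Mycn stood at 3.72, Sufu at 2.28, Nras at 1.71 and Ccnd1 at 2.67.

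Of 18 microglia genes 17 fell (18 adjusted over the list alone; camera adjusted p = 8.22e-18, and adjusted p = 0.151 with an estimated correlation). For the other cell type lists the brackets give, in this order, the falls adjusted over the list alone, the camera adjusted p and the adjusted p with an estimated correlation. Falls were seen in 10 of 15 astrocyte genes (10, 7.44e-09, 0.151), 9 of 13 fibroblast and meninges genes (11, 7.44e-09, 0.151), 10 of 15 endothelial and pericyte genes (12, 1.96e-08, 0.222) and 8 of 12 Purkinje cell genes (8, 9.85e-06, 0.222). They were seen in 8 of 16 neuronal differentiation genes (8, 5.74e-07, 0.151), 6 of 13 mature granule neuron genes (8, 3.9e-05, 0.287), 4 of 13 oligodendrocyte lineage genes (5, 0.0185, 0.498) and 2 of 3 red blood cell genes (2, 0.00524, 0.151). Of these lists only the oligodendrocyte one had a rise, 1 when adjusted over the list alone. Proliferation genes had a median of 2.09 and 4 rises in 32 (2 adjusted over the list alone; camera adjusted p = 0.000246, and adjusted p = 0.612 with an estimated correlation). Shh components rose in 4 of 8 (4 adjusted over the list alone; camera adjusted p = 0.0124, and adjusted p = 0.287 with an estimated correlation), and the Shh targets had 2 rises and 1 fall in 10 (6 and 1 adjusted over the list alone; camera adjusted p = 0.115). Against P6 cerebella alone the proliferation list had 17 rises and a median of 0.61, the Shh targets 4 rises and 0 falls and the mature granule neuron list 3 falls. The glycolysis list (camera adjusted p = 0.0858) passed there (0.0183). In all 2800 genes changed, 1614 higher and 1186 lower, 1437 at least 2-fold. Centred arrays gave 1020 higher and 1463 lower, with a shift of all genes by -0.13, and ended the camera call of the oligodendrocyte list. The count was 1768 without line SMB21 and 1646 without line SMB56.

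The changes of tumors and of SMB cells against the same cerebella shared 254 higher genes (56.5 by chance for independent lists) and 391 lower genes (61.4), with 18 and 11 genes called in opposite directions. In simulated unchanged groups with the same controls, lists of the same sizes, taken by the smallest p, shared 238.8 higher and 274.6 lower genes on average. The most they shared in 20 simulations was 257 higher and 301 lower genes. The 254 higher genes thus do not exceed the most shared by such lists, while the 391 lower genes do. In the simulated groups at most 2 genes were called for tumors and 1 for SMB cells, and 0 were shared. The simulated lists were thus almost wholly of genes that did not pass. They do not show that the 254 called genes come from shared controls. Across genes, which are not independent replicates, the changes correlated at r = 0.704, against 0.5 for simulated unchanged groups with the same controls. Their covariance was 0.532 against 0.064. With the P6 cerebella alone as control r was 0.644. The controls are too few to split, so part of the correlation and of the genes shared may also come from the shared controls.

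Growth factor culture (n = 3, 1 array per line) raised ERK feedback genes and lowered Gli1 and some granule neuron precursor genes against parental cells (n = 8). Dusp6, a phosphatase that inactivates ERK, rose by 1.93 (SE 0.34, adjusted p = 0.00385), from 10.78 (SD 0.55) to 12.67 (SD 0.53). Spry2, an inhibitor of receptor tyrosine kinase signalling, rose by 2.52 (SE 0.29, adjusted p = 0.000289) the related Spred1 by 1.09 (SE 0.15) and Spry4 by 1.05 (SE 0.27, adjusted p = 0.0276). Gli1 (-2.04, SE 0.46, adjusted p = 0.0127), Mycn (-2.57, SE 0.59, adjusted p = 0.0149) and Sfrp1 (-4.60, SE 0.47, adjusted p = 9.36e-05) fell. Atoh1 fell by 4.59 (SE 0.78, adjusted p = 0.0029) and Barhl1, a homeobox gene of granule neuron precursors, fell by 3.30 (SE 0.28, adjusted p = 1.3e-05). The extracellular matrix gene Tnc rose 37.7-fold (5.24, SE 0.44), the lipocalin Lcn2 58.9-fold (5.88, SE 0.88), the protease inhibitor A2m by 5.24 (SE 0.41) and Nap1l5 by 4.82 (SE 0.32).

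Of 20 ERK pathway targets 10 rose and 1, the ephrin receptor Epha4, fell (11 and 1 adjusted over the list alone; camera adjusted p = 6.99e-08, and adjusted p = 0.0731 with an estimated correlation). Invasion and mesenchymal genes rose in 9 of 30 (11 adjusted over the list alone; camera adjusted p = 6.99e-08, and adjusted p = 0.0836 with an estimated correlation), with Anxa1 at 3.30 (SE 0.46) and the hyaluronan receptor Cd44 at 3.02 (SE 0.46). Granule neuron precursor genes fell in 4 of 13 (7 adjusted over the list alone; camera adjusted p = 3.25e-05, and adjusted p = 0.19 with an estimated correlation). Glycolysis genes rose in 4 of 21 (10 adjusted over the list alone; camera adjusted p = 4.4e-07, and adjusted p = 0.243 with an estimated correlation). Neural stem and progenitor genes had 3 rises and 1 fall in 18 (10 and 2 adjusted over the list alone; camera adjusted p = 0.0017, and adjusted p = 0.0731 with an estimated correlation). Primary cilium genes had 1 fall in 10 (1 rise and 6 falls adjusted over the list alone; camera adjusted p = 0.018, and adjusted p = 0.0836 with an estimated correlation). Of 15 astrocyte genes 2 rose (2 adjusted over the list alone; camera adjusted p = 0.0165, and adjusted p = 0.195 with an estimated correlation). Other lists of cell types rose too, the endothelial and pericyte one in 1 of 15 (1 adjusted over the list alone; camera adjusted p = 0.0263, and adjusted p = 0.0836 with an estimated correlation) and the fibroblast and meninges one in 2 of 13 (2; 0.0292, and 0.348). Shh targets fell in 3 of 10 (4 adjusted over the list alone; camera adjusted p = 0.103; fry adjusted p = 0.00843), and receptors and RAS pathway genes rose in 3 of 15 (3 adjusted over the list alone; camera adjusted p = 0.0986). Proliferation genes had a median of -0.18, with 0 calls over all genes or adjusted over the list alone and a camera adjusted p of 0.172. Ptch1 (-0.48, SE 0.42), Ccnd1 (0.18, SE 0.19), Smo (-0.35, SE 0.14), Etv5 (0.68), Hhip (0.81), Nras (-0.23) and Sufu (-0.55) did not pass, and Sufu passed without the SMB55 GF array (-0.83, adjusted p = 0.0288).

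In all 1109 genes changed with growth factors, 494 higher and 615 lower, 518 at least 2-fold. This comparison rests on few arrays. With the replicate number as a block, which pairs each GF array with parental array 1 of its line, 243 genes passed, and Gli1 (-1.77, adjusted p = 0.0886), Mycn (-2.58, adjusted p = 0.112), Spry4 (1.02, adjusted p = 0.114) and Scg5 (-3.98, adjusted p = 0.0524) did not. In that fit the astrocyte list lost its camera call (0.0594) and the neuronal differentiation list gained one (0.0278). With 1 mean per line only 19 genes passed, and Gli1, Mycn, Atoh1, Dusp6, Spry2, Sfrp1, Lcn2, A2m, Anxa1 and Cd44 were among those that did not (adjusted p of 0.129, 0.214, 0.167, 0.113, 0.0549, 0.0735, 0.0735, 0.0735, 0.0971 and 0.0914). In that setting the endothelial and the fibroblast list lost their camera calls (0.05 each). Spry4 lost its call there (0.0861), with a pseudocount of 64 (0.0705), against the parental arrays numbered 1 alone (0.147), without the SMB21 or SMB56 GF array (0.125 and 0.129) and without line SMB21, SMB55 or SMB56 (0.0809, 0.0565 and 0.209). The count was 301 against the parental arrays numbered 1 alone, where Atoh1 had an adjusted p of 0.0523, Gli1 of 0.113 and Mycn of 0.121. It was 729 without the line as a term (Mycn 0.0593), 618 without the SMB21 GF array, 401 without the SMB56 GF array, 200 without line SMB21 and 306 without line SMB56. Without the SMB56 GF array the adjusted p of Gli1 was 0.117 and that of Mycn 0.105. Without line SMB21 it was 0.0911 for Gli1, 0.14 for Mycn, 0.171 for Atoh1, 0.0855 for Lcn2 and 0.072 for Cd44. Without line SMB56 it was 0.148, 0.15 and 0.0517 for the first 3 of these and 0.0518 for Dusp6.

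A test of the growth factor response by line passed for 174 genes (1551 at an unadjusted p under 0.05). It has 1 GF array per line, each assumed to vary like the replicates of the other groups, so it does not separate lines from single cultures. Atoh1 was among these genes. It changed by -6.34 in SMB21 and -6.14 in SMB56, but by -0.98 (SE 0.69) in SMB55 (adjusted p of the difference 0.0263). The neuroendocrine chaperone Scg5 changed by -5.78, -5.56 and -0.48 in the same order of lines (adjusted p = 0.00948). The count of 174 was 110 with the lowest genes left out, 328, 106, 79 and 65 without SMB21 parental replicate 1, 2, 3 and 4, 109 without SMB55 parental replicate 2 and 339 without SMB56 parental replicate 2.

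In RAS transformed cells (n = 7) granule neuron precursor genes fell and ERK targets and mesenchymal genes rose against parental cells (n = 8). Atoh1 fell by 6.45 (SE 0.59, adjusted p = 3.71e-06), from 12.51 (SD 0.38) to 6.08 (SD 0.80), close to the lowest intensities on the arrays. Gli1 fell by 2.75 (SE 0.35, adjusted p = 4.93e-05). Mycn (-3.80, SE 0.45), Sfrp1 (-4.35, SE 0.36), the Hedgehog effector Gli2 (-2.45, SE 0.32) and Smo (-1.04, SE 0.11, adjusted p = 9.12e-06) fell as well. Dusp6 rose by 2.78 (SE 0.26, adjusted p = 4.39e-06), to 13.54 (SD 0.54), the immediate early gene Egr1 by 3.18 (SE 0.31), Spry4 by 1.80 (SE 0.21) and Ccnd1 by 1.10 (SE 0.15). Anxa1, a phospholipid-binding annexin, rose 149-fold (7.21, SE 0.35, adjusted p = 1.61e-08), and the cytokine Il33 43.2-fold (5.43, SE 0.21).

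ERK targets rose in 15 of 20 and fell in 1, Epha4 (17 and 1 adjusted over the list alone; camera adjusted p = 4.75e-11, and adjusted p = 0.025 with an estimated correlation). Invasion and mesenchymal genes rose in 20 of 30 and fell in 1, the transcription factor Zeb1, a driver of epithelial to mesenchymal transition (22 and 1 adjusted over the list alone; camera adjusted p = 1.1e-12, and adjusted p = 0.0369 with an estimated correlation). With all arrays, these were the only camera calls of the 6 comparisons that held with an estimated correlation. With 1 mean per line neither did (0.236 and 0.422), and with the parental arrays numbered 1 left out the invasion list did not (0.0665). Other calls held in other selections of arrays. Against P6 cerebella alone these were the astrocyte, Purkinje cell, endothelial and fibroblast lists in medulloblastoma (0.028 each) and in SMB cells (0.0301 to 0.0434), and against the parental arrays numbered 1 alone the ERK targets with growth factors (0.0454). Cd44 rose by 4.19 (SE 0.35), Tnc by 4.06 (SE 0.34) and the metalloproteinase inhibitor Timp1 by 5.47 (SE 0.67). Fibroblast and meninges genes rose in 7 of 13 and fell in 1 (7 and 1 adjusted over the list alone; camera adjusted p = 0.000328, and adjusted p = 0.217 with an estimated correlation), with Foxc1 at 2.87 (SE 0.27) and the collagen Col5a1 at 2.27 (SE 0.34). Single markers of other cell types rose as well, Gja1 by 4.89 (SE 0.52) and Cd68 by 2.25 (SE 0.43), while the astrocyte list had 1 rise in 15 (1 adjusted over the list alone; median -0.01, mean 0.60, upward test, camera adjusted p = 0.286). The microglia list had 4 in 18 (4; median -0.01, mean 0.27, upward test, 0.209) and the endothelial list 4 in 15 (4; median -0.02, mean 0.56, upward test, 0.13).

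Granule neuron precursor genes fell in 10 of 13 (10 adjusted over the list alone; camera adjusted p = 3.32e-06, and adjusted p = 0.217 with an estimated correlation), with Barhl1 at -3.43 (SE 0.22) and Nhlh1 at -3.36 (SE 0.30). Neuronal differentiation genes had 7 falls and 3 rises in 16 (9 and 3 adjusted over the list alone; camera adjusted p = 0.0126, and adjusted p = 0.296 with an estimated correlation). Dcx, a microtubule protein of migrating neurons, fell by 4.56 (SE 0.37) and the neuronal RNA-binding protein gene Elavl3 fell by 3.48 (SE 0.19). Proliferation genes fell in 24 of 32 (26 adjusted over the list alone; camera adjusted p = 2.58e-07, and adjusted p = 0.307 with an estimated correlation) with a median of -0.61, for example the replication genes Mcm6 (-0.86, SE 0.14) and Pcna (-0.65, SE 0.11) and the cyclin Ccna2 (-1.19, SE 0.21). Of the Shh components 5 of 8 fell and 1 rose (6 and 1 adjusted over the list alone; camera adjusted p = 0.0157, and adjusted p = 0.307 with an estimated correlation), with the negative regulator Sufu at -0.83 (SE 0.16). Shh targets had 3 falls and 2 rises in 10 (4 and 2 adjusted over the list alone; camera adjusted p = 0.513; fry adjusted p = 0.00627, downward). Glycolysis genes rose in 6 of 21 (6 adjusted over the list alone; camera adjusted p = 0.000292, and adjusted p = 0.367 with an estimated correlation), led by the phosphofructokinase Pfkp at 3.87 (SE 0.35). Receptors and RAS pathway genes had 7 rises and 1 fall in 15 (7 and 1 adjusted over the list alone; camera adjusted p = 0.0565). Interferon genes rose in 3 of 17 (1 adjusted over the list alone; camera adjusted p = 0.0125, and adjusted p = 0.517 with an estimated correlation). The p53 targets had 4 rises and 5 falls in 15, with a median of -0.22, a mean of 0.10 and a downward test (4 and 5 adjusted over the list alone; camera adjusted p = 0.83), and Wnt targets 2 rises and 3 falls in 11 (3 and 3; 0.812).

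Hhip (0.13) and Nras (-0.39) did not pass, nor did Etv5 (0.68, adjusted p = 0.0811) and Ptch1 (-0.87, SE 0.32, adjusted p = 0.0505). Nras passed without line SMB56 (-0.61, adjusted p = 0.0431), and Etv5 passed without SMB21 RAS replicate 3 (0.88, adjusted p = 0.0179), SMB21 parental replicate 4 (0.78, adjusted p = 0.0491) or line SMB21 (1.18, adjusted p = 0.0275). Ptch1 stood close to the threshold. It passed without the SMB21 GF (0.025), SMB56 GF (0.0282), SMB21 RAS 3 (0.0429), SMB21 parental 4 (0.0421), SMB56 parental 2 (0.037) or SMB56 RAS 2 (0.0165) array and without line SMB56 (0.018), and also with centred (0.034) or quantile normalised (0.0455) arrays.

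In all 3974 genes changed with RAS, 1750 higher and 2224 lower, 1302 at least 2-fold. The count was 667 with 1 mean per line, where Mycn had an adjusted p of 0.0614, Timp1 of 0.0575, Gli2 of 0.0575, Ccnd1 of 0.0559, Sufu of 0.1, Mcm6 of 0.0522, Ccna2 of 0.0607 and Cd68 of 0.107, and the interferon list lost its call (0.132). It was 2548 without line SMB55. Within single lines 2409 genes changed in SMB21, 2666 in SMB55 and 1492 in SMB56. The change of Gli1 in these lines was -2.37, -3.38 and -2.77, and that of Atoh1 -6.71, -6.46 and -5.91. The response differed by line in 428 genes (2600 at an unadjusted p under 0.05), among them Anxa1 with 8.26, 6.61 and 5.97 (adjusted p of the difference 0.02), Gli2 with -1.52, -2.73 and -3.75 (0.0106) and Timp1 with 6.73, 6.81 and 2.02 (0.0199). That count ran from 190 without SMB56 RAS replicate 2 to 1230 without SMB56 parental replicate 2. It was 274, 215 and 240 without SMB21 parental replicate 2, 3 and 4, 653 without SMB21 RAS replicate 1, 257 and 266 without replicate 1 of SMB55 parental and SMB55 RAS, and 249 without SMB56 RAS replicate 1. Nothing says which cultures the RAS arrays of a line came from, so this test does not separate lines from cultures either. SMB56 had the smallest change of Timp1 and the largest of Gli2. Its RAS arrays, as deviations from the mean of the lines, correlated at 0.161 with its own parental arrays. With those of another line it was 0.336.

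**Figure D2:**
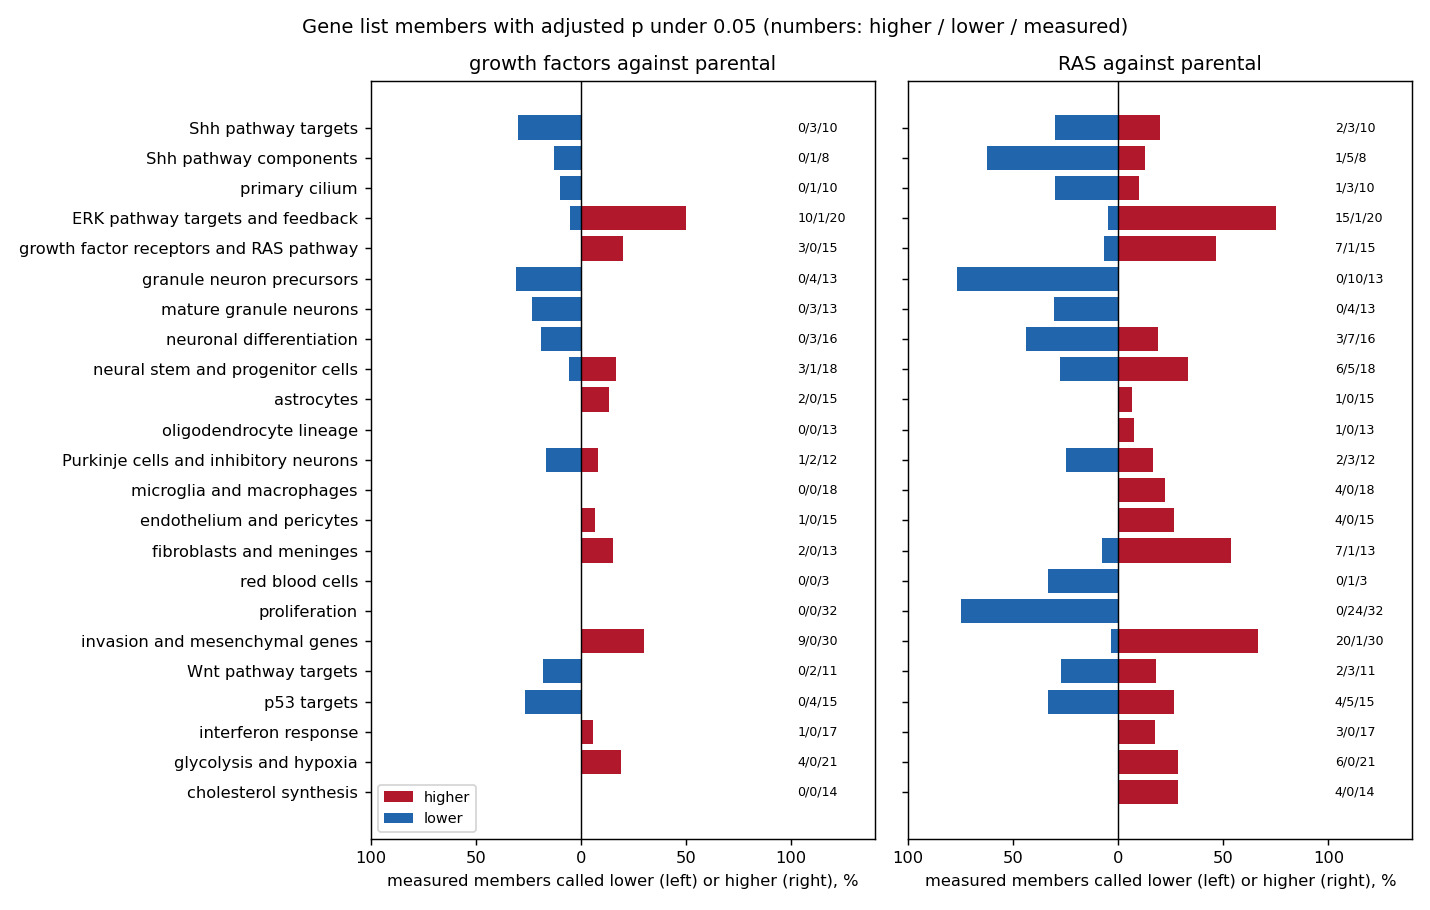
Share of the measured members of each gene list, in percent, called higher or lower with growth factors or with RAS against parental cells. Numbers give the members called higher, called lower and measured, for example 15, 1 and 20 for ERK targets with RAS.

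Growth factor and RAS cells shared 294 higher genes (69.8 by chance for independent lists) and 404 lower genes (110.4), with 4 and 7 called in opposite directions. With the parental arrays split between the comparisons, 117 higher (16.8) and 107 lower genes (19.6) were shared. Simulated unchanged groups made at most 2 calls in a comparison and shared 0, and their lists of the same sizes as with all arrays, taken by the smallest p, shared 203.1 higher and 279 lower genes on average. Across genes, which are not independent replicates, r was 0.608 against 0.36 for simulated groups, and the covariance 0.284 against 0.024. With split parental arrays r was 0.62 and the covariance 0.301.

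Between RAS cells (n = 7) and growth factor cells (n = 3) some invasion genes were higher and some proliferation genes lower, and no difference in Gli1 or Atoh1 passed. Anxa1 was higher by 3.92 (SE 0.47, adjusted p = 0.000472), the matrix protein Thbs1 by 3.10 (SE 0.42), the chromatin protein Hmga2 by 3.42 (SE 0.37), Gja1 by 4.31 (SE 0.70) and Aldh1a3, an enzyme of retinoic acid synthesis, by 4.41 (SE 0.47, adjusted p = 0.000242). Pmepa1, a regulator of TGF-beta signalling, was higher by 4.48 (SE 0.69). Nap1l5 (-5.27, SE 0.32, adjusted p = 8.38e-07), A2m (-5.10, SE 0.41), the selenium carrier Selenop (-3.74, SE 0.55) and the EGF receptor Egfr (-1.15, SE 0.20) were lower in RAS cells. Gli1 (-0.71, SE 0.46, adjusted p = 0.324), Atoh1 (-1.86, SE 0.79), Ptch1 (-0.40), Etv5 (0.00), Hhip (-0.67), Sufu (-0.28), Nras (-0.16), Spry4 (0.75), Dusp6 (0.85) and Mycn (-1.23) did not pass. The last 2 passed without the SMB56 GF array (Dusp6 1.37, adjusted p = 0.0331; Mycn -2.37, adjusted p = 0.0137), and Spry4 without SMB21 RAS replicate 3 (0.91, adjusted p = 0.0132). Ccnd1 was higher in RAS cells (0.91, SE 0.20, adjusted p = 0.0105) and Smo lower (-0.69, SE 0.14, adjusted p = 0.00853). The call of Ccnd1 was lost without the SMB21 GF array (0.0609) and without line SMB21 or SMB55 (0.0783 and 0.11), that of Smo without the SMB55 GF array (0.0703), without line SMB55 (0.116) and without the line as a term (0.09), and both with 1 mean per line (0.122 and 0.0898).

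Proliferation genes were lower in 7 of 32 (14 adjusted over the list alone; camera adjusted p = 0.000104, and adjusted p = 0.594 with an estimated correlation). Invasion genes were higher in 7 and lower in 2 of 30 (10 and 3 adjusted over the list alone; camera adjusted p = 0.00193, and adjusted p = 0.594 with an estimated correlation). ERK targets had 4 higher and 1 lower of 20 (4 and 1 adjusted over the list alone; camera adjusted p = 0.0508; 0.0199 with 1 mean per line). Granule neuron precursor genes had 0 calls over all genes or adjusted over the list alone, with a camera adjusted p of 0.111. Shh targets had 2 higher of 10 (3 adjusted over the list alone), a median of -0.34, a mean of 0.03 and an upward test (camera adjusted p = 0.654). In all 1383 genes differed, 707 higher and 676 lower in RAS cells, 569 at least 2-fold, and centred arrays gave 591 higher and 1017 lower. The count was 898 with the parental arrays left out of the fit, 781 without the line, 53 with 1 mean per line, 457 and 769 without the SMB55 and SMB56 GF array and 222 without line SMB55. With 1 mean per line Anxa1, Thbs1, Gja1, Aldh1a3, Pmepa1, A2m and Selenop no longer passed (adjusted p of 0.0618, 0.0621, 0.0631, 0.0603, 0.087, 0.059 and 0.0573). In sample order, GF arrays stand among the parental arrays numbered 1 and RAS arrays among the other parental arrays. No label names a batch. In a limma fit with the line as a term, 2142 genes differed between these parental sets at an unadjusted p under 0.05. At an adjusted p under 0.05 it was 2. A difference between these sets of arrays cannot be told apart from that of RAS and GF cells.

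Whole chromosomes moved together in some of these differences. Against P6 cerebellum, the genes of chromosome 13 had a median of -0.78 in parental SMB21 and -0.53 in SMB56, and those of chromosome 6 of 0.36 in SMB21 and 0.35 in SMB55. Against their parental lines, RAS cells of SMB55 and SMB56 had chromosome 15 higher by 0.50 and 0.39, chromosome 14 at -0.35 and -0.43 and chromosome X at -0.41 and -0.59. Some of these depend on the parental array. Against parental replicate 1 and 2 alone, SMB56 RAS cells had chromosome 14 at -0.63 and -0.22, chromosome 7 (0.36 against both) at 0.68 and 0.03 and chromosome 18 (-0.34) at -0.56 and -0.11, and SMB55 RAS cells had chromosome X at -0.51 and -0.22. Of the 16 medians of at least 0.3 with RAS or growth factors 5 reached 0.3 against each parental array of the line, and of the 11 of parental lines against P6 cerebellum 5 did so in each array. SMB56 parental replicate 1 differed from replicate 2 by -0.63 on chromosome 7, -0.38 on chromosome 10, 0.40 on chromosome 14 and 0.41 on chromosome 18, and SMB21 parental replicate 1 from the other SMB21 arrays by -0.35 on chromosome 15 and 0.32 on chromosome 19. The counts with growth factors and with RAS were 946 and 3166 without the genes of chromosomes 6, 13, 14, 15 and X.

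**Figure D3:**
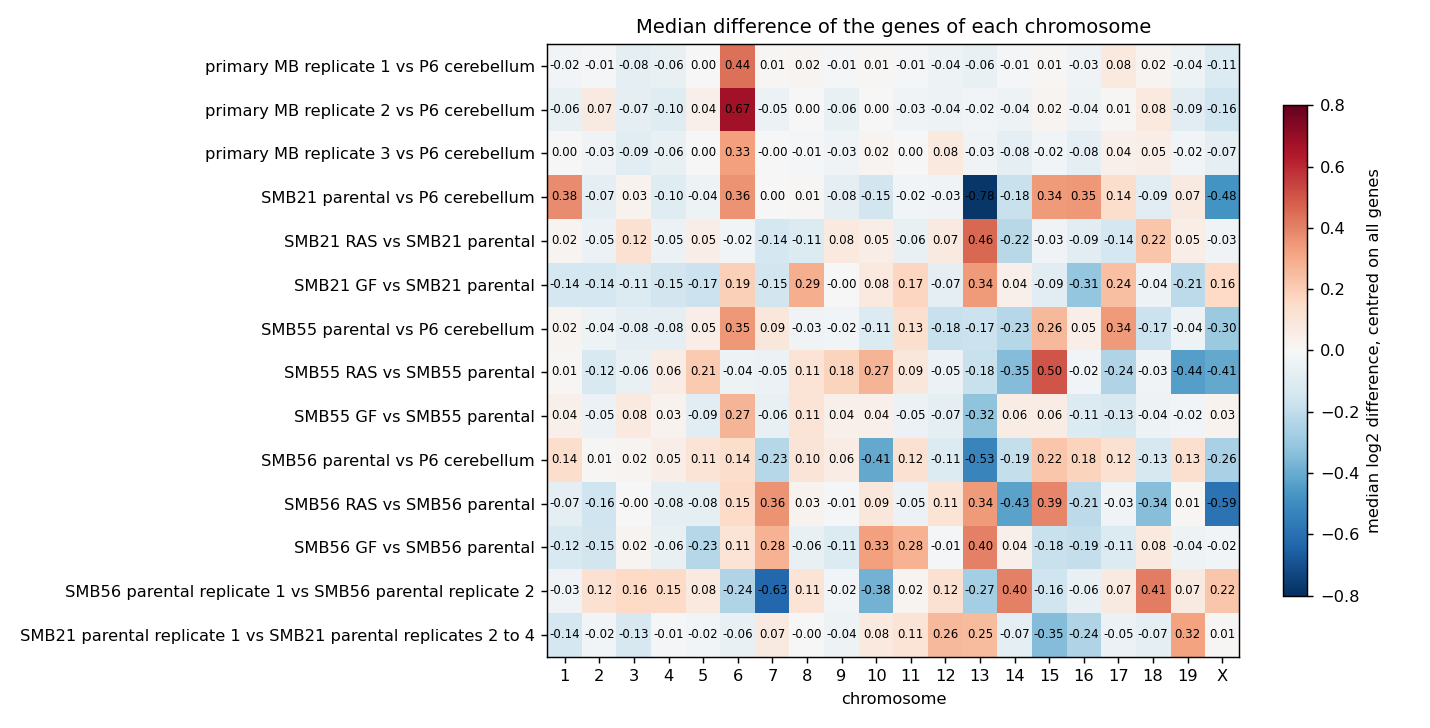
Median log2 difference of the genes of each chromosome, centred on all genes, for 14 differences between samples. Chromosome 6 is raised in the 3 tumors, by 0.33 to 0.67, and chromosomes 7 and 10 are lowered in SMB56 parental replicate 1 against replicate 2.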

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

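The tests of the chromosome shifts with RAS or growth factors, of the Y-linked genes of SMB56 parental replicate 1, of single parental arrays as the reference for chromosomes, of both explanations for SMB55, and of the growth factor response by line were chosen only after the result was seen.

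A test of the response by line passed for 428 genes with RAS and, with 1 GF array per line, for 174 with growth factors. In neither case does it separate lines from cultures. Of the 85 genes printed in this text, without the Y-linked ones, it passed with growth factors for Bex1 (adjusted p = 4.15e-08), A2m (0.00071), Zic5 (0.00155), Dll3 (0.00936), Scg5 (0.00948), Atoh1 (0.0263), Cbln1 (0.0277), Gli2 (0.0297) and Anxa1 (0.0372). With RAS it passed for Zic5 (0.00282), Pdgfrb and Pmepa1 (0.00315 each), Aldh1a3 (0.0093), Gli2 (0.0106), Timp1 (0.0199), Anxa1 (0.02), Foxm1 (0.0232), Rgs5 (0.0355) and Dll3 (0.0485). Among the 4 parental SMB21 arrays, 7 of the 85 had 1 array far from the rest by Dixon's limit, where chance gives about 1 in 20. In all 7 it was replicate 1, with Neurod1 at 12.32, Stmn2 at 8.67, Aqp4 at 6.63 and Sufu at 10.39 above the others, and Epha4 at 7.59, Fdps at 11.47 and Nras at 11.69 below them. Of the 2246 probe sets without a single symbol, which no comparison used, 648 changed with RAS, 224 higher and 424 lower, and 75 with growth factors.

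Whole chromosomes shifted in 14 medians against P6 cerebellum and in 16 with RAS or growth factors, each by at least 0.3, but only 5 of these 16 reach 0.3 against each parental array of the line, and chromosome 7 in SMB56 RAS cells stands at 0.68 against parental replicate 1 and at 0.03 against replicate 2. Random gene lists of the same brightness reached such a shift in 0% of 10000 draws in both sets, so probe brightness alone did not give shifts of this size. The draws used the same normalized values, and the chromosome medians were not computed under another normalization. Normalization as a cause is therefore not tested. The test of dose, that each of 3 equal parts of the chromosome moves the same way by at least 0.1, was written for all 30 shifts together, gave -0.06, and was only then split. Against P6 cerebellum 13 of the 14 shifts met this test. Chromosome 15 in SMB21 fell short, with -0.06 in its first part. That value has no error, and random gene lists for this shift reached up to 0.22. The median of this chromosome was 0.06 in SMB21 parental replicate 1 and 0.39 to 0.46 in replicates 2 to 4. The -0.06 therefore does not decide whether dose of the whole chromosome underlies all 14 shifts. With RAS or growth factors the lowest part moved by 0.15. A change in chromosome dose may underlie those shifts as a hypothesis, in treated or in parental cells. The tumor, the line and the treatment remain open as causes, untested.

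SMB56 parental replicate 1 differs from replicate 2 by chromosomes 7, 10, 14 and 18, of which 14 and 18 lie higher in it (0.40 and 0.41). Counted by genes on in 1 array and off in the other, it lies 93 from replicate 2 and 46 from its nearest array of another line, SMB21 parental replicate 3. Any number under 93 was first taken as agreeing with a mislabelled line, but 46 is above the 31 at most within SMB21 or SMB55 and within the 12 to 94 seen between lines, so after it was seen it was read as undecided. The 31 comes from SMB21 parental replicate 1, which lies 26 to 31 from the other SMB21 parental arrays. It lies as near, at 26, to SMB55 parental replicate 1. The remaining pairs within SMB21 or SMB55 differ by 0 to 5. The Y-linked genes Kdm5d and Uty stand at 8.73 and 8.65 in SMB56 parental replicate 1, near the SMB56 GF array (8.26 and 8.35). These levels are far from SMB21 parental replicate 3 (4.93 and 4.95) and all SMB55 arrays (at most 5.16), which speaks against those labels. SMB21 parental replicate 1 has 9.14 and 7.97 but differs in the third Y-linked gene, Eif2s3y. That gene stands at 4.93 in SMB56 parental replicate 1 and 5.06 in the SMB56 GF array. In SMB21 parental replicate 1 it stands at 9.54 and in SMB56 parental replicate 2 at 9.23. The label stays open, for chromosomes 7 and 10 alone their loss in that culture may account for the difference, since each of 3 parts lies at -0.32 or below, replicate 2 itself lies nearer to both SMB55 arrays (12 and 25) than to replicate 1, and the design names no group to test a biological difference with.

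The fall of Atoh1 with growth factors was -0.98 in SMB55 against -6.34 in SMB21 and -6.14 in SMB56. Untreated cells in that culture would need a share of 48.8% to give this level. The first test asked whether ERK targets rose there by no more than 0.512 of their rise in the other lines; the median ratio was 0.733 (quartiles 0.594 and 0.807), above 0.512 in 8 of 10, which by its rule excluded untreated cells, but that bound assumes that the lines respond alike, so it was replaced after this value was seen. The second found 8 genes that fell in SMB55 below the untreated share by more than 2 SE, short of the 10 set to exclude untreated cells; any smaller number was first taken as agreeing with them, and only after the 8 was seen was 1 to 9 read as undecided, so they are left open here beside a difference between the lines. For the latter, 2 precursor genes, Atoh1 and Zic5 (2.85 in SMB55, -2.50 and -2.57 in the others), differed by line, with 1 array per line to judge by.

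Other splits of the samples bear on the counts of changed genes. For medulloblastoma against normal cerebellum (1076, highest other 0), SMB cells against medulloblastoma (1373, 1) and SMB cells against normal cerebellum (2800, 2), the 10 splits are too few for a share under 0.05. With growth factors the 8 splits that part all 3 pairs of a GF array and parental array 1 are also too few (1109, highest other 15), and the other 37 of the 45 gave at most 2. With RAS 1 of 100 drawn splits, the real one, gave as many (3974, highest other 11), and between RAS and growth factors 1 of 36 (1383, highest other 107). In both comparisons of RAS cells the real groups thus gave more changed genes than any other split tried. The splits exchanged single arrays of a line as if these were independent. Nothing says which cultures the arrays came from, so the splits cannot exclude chance differences between cultures or lines.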

How the results depend on the processing

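The settings with P6 cerebella counted as 1 sample, SMB21 parental replicates 3 and 4 as 1 array, genes of 5 chromosomes left out, other controls and the replicate block for the gene lists, single parental arrays for the chromosome shifts, and all of those for the growth factor response by line were chosen after seeing the data. Signal over background limits the calls of genes near the lowest intensities, whose changes are compressed, and omission of the lowest genes leaves fewer to test. In fits that leave a group with 1 array, as with the adult cerebellum alone as control, that array is assumed to vary like the other groups. The counts of those fits rest on this assumption. No call of a named gene or list and no agreement of changes was reversed in any setting run.

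Counts of changed genes moved by over 1.5 times in these settings, and unless stated the cause was not tested. A 2-fold limit, which by its construction only removes genes, left 649 for medulloblastoma against normal cerebellum, 694 for SMB cells against medulloblastoma, 1437 for SMB cells against normal cerebellum, 518 with growth factors, 1302 with RAS and 569 between RAS and growth factors. For medulloblastoma the adult cerebellum alone gave 3066 and P6 counted as 1 sample, with fewer samples, 514. With 1 mean per line, 19 genes passed with growth factors, 667 with RAS and 53 between these. That setting has fewer samples and takes the line as the replicate, whereas the main fit of cultures counts arrays of 1 line as separate replicates. Without the line the counts were 729 with growth factors and 781 between RAS and growth factors. The parental arrays numbered 1 alone, again fewer samples, gave 301 with growth factors, and a fit of only the 2 groups gave 898 between RAS and growth factors. The growth factor response by line was 110 without the lowest genes. In the other settings that use all arrays or probe sets differently, the counts stayed within 1.5 times, at 729 to 1361, 1065 to 1721, 1903 to 3832, 886 to 1125, 3025 to 4268 and 1282 to 1608 in the order of the 6 comparisons. The counts within lists fell in the same way. With 1 mean per line 0 ERK targets rose with growth factors, and with RAS 9 invasion genes rose and 4 proliferation genes fell. The agreement of tumor and SMB changes, 0.704, was 0.644 with P6 cerebella alone, a move of over 1 SD of the values with single arrays left out.

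Leaving out each array or line in turn gave 409 to 1361 genes for medulloblastoma against normal cerebellum, 589 to 2553 for SMB cells against medulloblastoma, 1646 to 3176 for SMB cells against normal cerebellum, 200 to 1190 with growth factors, 2548 to 4124 with RAS and 222 to 1659 between these. The response by line ranged from 190 to 1230 for RAS and from 65 to 339 for growth factors, and the agreements from 0.644 to 0.75 and from 0.505 to 0.647. In the order of the comparisons, 27 of 60, 22 of 57, 15 of 71, 40 of 52, 13 of 75 and 32 of 46 called named genes lost the call in at least 1 of these fits.

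No label ties a replicate number to a culture or animal. Only for growth factors did all pairs of the same number correlate above 0.1, but those deviations keep the line, which the paired arrays share. The deviations for RAS against parental cells leave the line out, so the 2 sets of values do not show a difference in pairing. With the replicate number as a block within lines, 243 genes passed with growth factors, 161 between RAS and growth factors, and 415 for medulloblastoma against P6 cerebellum. With RAS it was 3175, within 1.5 times. For growth factors it ended or made no call of a gene or list that the report gives beyond those named there. Pairs with the same number correlated at -0.154 to -0.020 for RAS, 0.204, 0.018 and 0.137 between RAS and growth factors, and -0.028 and 0.005 for tumors and P6 cerebella.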

Other observations

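Lists that the text has not yet described moved between medulloblastoma (n = 3) and normal cerebellum (n = 3) as well. In brackets stand the numbers adjusted over the list alone, the camera adjusted p and the adjusted p with an estimated correlation. Endothelial and pericyte genes fell in 2 of 15 (8, 0.000193, 0.631), with Pdgfrb at -2.49 (SE 0.20), oligodendrocyte genes in 3 of 13 (6, 0.00307, 0.631) and red blood cell genes in 2 of 3 (2, 0.00305, 0.178). Against P6 cerebella alone 10 endothelial and pericyte genes fell (median -1.11, camera adjusted p = 3.72e-09) and 8 cholesterol synthesis genes (median -0.63, 1.61e-05). Cholesterol synthesis genes fell in 3 of 14 (3, 0.0116, 0.631), with Msmo1 at -1.15 (SE 0.15), where SMB cells against normal cerebellum had 6 rises (7 and 1 fall, 0.00524, 0.498). Glycolysis genes had a median of -0.56 and 1 rise and 1 fall in 21 (1 and 1, 0.0187, 0.631). Against P6 cerebella alone the camera adjusted p of that list was 0.154. Granule neuron precursor genes had 1 rise in 13, that of Boc (4 and 1 fall, 0.0187, 0.631), with 4 rises and 0.0715 against P6 cerebella alone.

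The test fry, which does not refer to other genes, passed for 6, 7, 14, 13, 16 and 2 lists in the order of the comparisons in the report, where camera passed for 12, 8, 13, 9, 9 and 2, and both passed for 5, 6, 11, 8, 8 and 0. For medulloblastoma against normal cerebellum fry gave adjusted p of 0.0818 for microglia, 0.235 for proliferation, 0.0502 for endothelium, 0.157 for granule neuron precursors, 0.0895 for oligodendrocytes, 0.176 for cholesterol and 0.225 for glycolysis. Other camera calls without fry were those of precursors (0.117) and mature granule neurons (0.185) in SMB cells against medulloblastoma, and of oligodendrocytes (0.135) and proliferation (0.115) against normal cerebellum. Further ones were fibroblasts with growth factors (0.0749), interferon with RAS (0.099), and proliferation (0.0693) and invasion (0.0533) between these. In the other direction, fry alone passed for receptors and RAS pathway genes, upward, in all comparisons (0.0452, 0.0409, 0.00184, 0.00843 and 0.000173) except that of RAS with growth factors. It alone passed for Shh targets, upward in SMB cells against normal cerebellum (0.0252) and downward with growth factors and RAS, for neuronal differentiation (0.034) and p53 targets (0.0102) with growth factors, both downward, and for mature granule neurons (0.000336), Purkinje cells (0.00219) and red blood cells (0.00357) with RAS, all downward. The rest of its own calls were upward ones of glycolysis in SMB cells against normal cerebellum (0.0291), microglia with growth factors (0.0404), stem cells (0.000174), microglia (0.0375) and endothelium (0.00123) with RAS, and, between these, cilium genes upward (0.0247) and red blood cell genes downward (0.0029).

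The Y-linked genes Eif2s3y, Kdm5d and Uty differ between arrays of 1 line. In SMB21 parental replicate 1 and the SMB21 GF array, Kdm5d stands at 9.14 and 8.86, and in SMB21 parental replicates 2, 3 and 4 at 5.00, 4.93 and 5.02. In SMB21 RAS replicates 1, 2 and 3 it stands at 5.02, 4.9 and 4.95. In SMB56 parental replicate 1, parental replicate 2 and the GF array it stands at 8.73, 8.25 and 8.26, and in SMB56 RAS replicates 1 and 2 at 4.88 and 5.13. In SMB21 and SMB56 the comparison of RAS with GF cells thus cannot be told apart from this difference between arrays. The same holds for RAS against parental cells in SMB56. In SMB21 it holds for GF cells against parental replicates 2, 3 and 4, and for RAS cells against parental replicate 1. Among the primary tumors Kdm5d stands at 8.82, 5.14 and 8.94 in tumors 1, 2 and 3. Eif2s3y stands at 4.93 in SMB56 parental replicate 1 and at 9.23 in replicate 2. These 3 genes were looked at after the data were examined.

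The mean deviation of each line among RAS or GF arrays was correlated across genes with that of each line among parental arrays. In 5 of the 6 cases the own line was highest. For SMB56 RAS it was 0.161 with the parental arrays of its own line and 0.336 with those of another line. The line term of every fit of cultures follows the labels, and the RAS count was 3364 without line SMB56 and 3349 without the line term.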
